A study of Homo sapiens with 4 samples.

How the data were processed

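Gene expression was measured in MiaPaCa2 cells on Human Gene 1.0 ST arrays, 1-colour oligonucleotide arrays whose probe sets each summarise many short probes along a transcript. Per the labels, 2 arrays held RNA from vehicle-treated cultures and 2 held RNA from cultures given LY101-4B at 50 µM, all for 24 h, and the series' design calls the 2 samples of each group biological replicates. The treatment protocol attached to the same samples instead names LY101-4D at 25 µM; the sample titles, the agent labels and the design text all give LY101-4B at 50 µM, and these were followed. Per the labels' protocols, total RNA was biotin-labelled with a FlashTag Biotin HSR kit before hybridisation; such kits are usually used for small RNA, and whether this entry describes these arrays is uncertain. The deposited table holds log2 expression values per probe set that the submitters' processing notes credit to RMA, a procedure that corrects background, quantile-normalises probes and summarises them per probe set; the software version, the probe set definitions and any filter are not given in the sources used here. RMA forces arrays to nearly the same distribution, so changes are relative to the bulk of probe sets, and it compresses differences at low signal. The column medians lay between 5.88 and 5.97 log2 units. No detection calls or scanner files were used here, so no probe set was called absent.

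The table had 33297 rows. Genes were assigned from the platform annotation, with symbols checked through gene identifiers against a RefSeq gene table of assembly GRCh38.p14 used for names only; 0 symbols needed updating and 31 single-gene probe sets had an identifier with no row there. Of all rows, 19460 probe sets had 1 gene symbol, 1754 had several and 12083 had none. The 21214 probe sets with at least 1 symbol were tested; only those with 1 symbol were named. They covered 18417 genes, and for the 769 genes with more than 1 probe set the one with the highest mean over the 4 arrays stood for the gene. Among genes named below, dimmer probe sets of BIRC5, BOP1, KRT18 and SDHD were also called lower, but by less (1.35-fold, 1.68-fold, 1.38-fold and 1.38-fold). Those of CYP51A1 and IER3 were called higher, by 2.58-fold and 1.75-fold, close to the values given. All columns of the table were mapped to samples (0 were left unmapped).

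A linear model with the treatment as its only term was fitted to the 4 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, not robust), and 2-sided p-values were adjusted over the tested probe sets by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior worth 3.75. Differences are LY101-4B minus vehicle on the log2 scale with the moderated standard error (SE), and group values are means ± SD over n = 2 arrays. Array number limits the precision. Sets of genes were tested with limma's camera, with a preset inter-gene correlation of 0.01 and adjustment over 33 lists. These lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. Where camera estimates the correlation from the arrays, it works with the 2 residual degrees of freedom, and none of the 33 lists passed (smallest adjusted p 0.289). By fry, limma's rotation test of whether a list moves one way on balance, 23 lists passed. Lists share some genes (E2F1, E2F2, E2F8 and RBL1 stand on both E2F lists), and 739 of 812 list entries were measured; the others are not analysed here. The result of 1 of the 33 lists is not reported here, though it stays in the counts of lists and in the adjustment.

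Genes were named by this rule: every measured member of the E2F and pocket protein list; the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, leaving out uncharacterised loci; and from each reported list up to 4 called members with the largest change, or the 2 with the smallest p where none was called. Genes named outside the rule are marked.

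The fit was tested on simulated data in 20 draws, each with 200 of 21214 probe sets changed. With variances drawn from the fitted prior, it recovered on average 2.5% of probe sets changed by 0.5 log2 units, 79.9% of those changed by 1, 98.8% of those changed by 2 and 99.6% of those changed by 3. A mean of 4.27% of calls were false, from 1.39% to 8.97% over the draws. With each probe set's own moderated variance it recovered 57.9% at 0.5 and 100% at 1, 2 and 3, but a mean of 8.05% of calls were false, from 2.78% to 14.2%, and 14 of the 20 draws exceeded the nominal 5%. False calls among the probe sets can thus be more frequent than the threshold states. The variance drawn from the prior was added after a first draw with the other variances had given the 14.2%. In a simulation of 18417 genes, camera with the preset correlation called a list of 40 genes shifted by -0.5 and 0 of 20 unshifted lists. With an estimated correlation it missed the shifted list (adjusted p 0.0688). The simulated genes were independent of each other, so this does not test how the preset correlation behaves where genes vary together.

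Alternatives were a replicate-number block, cyclic loess, median centring, a filter keeping the brighter 50% of probe sets, a trend or robust prior, each array left out in turn, all rows, 1 probe set per gene, a 2-fold minimum, averaged probe sets and other set tests; restricting the test to single-symbol probe sets was added after seeing the data. The labels number the replicates in each group, but nothing says that equal numbers share a culture or a day, so the arrays were treated as unpaired. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.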

Results

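Transcript levels were profiled in MiaPaCa2, a human pancreatic ductal adenocarcinoma line, after 24 h with vehicle (2 arrays) or with LY101-4B at 50 µM (2 arrays); a protocol text of the same samples names another code and dose, LY101-4D at 25 µM. The series presents LY101-4B as an inhibitor of E2F, the family of transcription factors that drives entry into S phase, and asks how sensitive these cells are to it. Each array gave 33297 log2 RMA values with a median between 5.88 and 5.97. The vehicle arrays correlated at r = 0.997 and the LY101-4B arrays at r = 0.994 across the 21214 gene-annotated probe sets, whereas r between groups ranged from 0.978 to 0.981. Differences between replicate arrays had an SD of 0.164 log2 units for vehicle and 0.223 for LY101-4B.

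The largest fall with LY101-4B was that of FAM111B, a protease gene expressed with the cell cycle, from 8.66 ± 0.18 to 5.34 ± 0.43 log2 units (SD, n = 2 each), which is 9.99-fold. It was followed by CLSPN, the replication checkpoint adaptor claspin (7.62-fold), the linker histone H1-5 (7.28-fold), the replicative helicase factor GINS2 (6.23-fold), H2BC14 (5.65-fold), MCM10 (5.54-fold), H2AC4 (5.53-fold), MCM5 (5.12-fold), H3C2 (5.02-fold), the DNA polymerase epsilon subunit POLE2 (4.99-fold), WDR76 (4.88-fold) and H2BC7 (4.76-fold). Another, dimmer CLSPN probe set fell 5.24-fold, so the rank of CLSPN depends on the probe set. The largest rise was that of NIBAN1, a stress-induced gene, from 5.93 ± 0.03 to 10.1 ± 0.15 log2 units (SD, n = 2 each), or 18.3-fold. The stress cytokine GDF15 rose 16.1-fold, DDIT3, which encodes the stress transcription factor CHOP, 11.8-fold and SLFN5 10.8-fold. The autophagy gene WIPI1 rose by 3.59 log2 units. NMRAL2P rose 8.77-fold, the hexokinase-like gene HKDC1 8.49-fold, the mitochondrial folate enzyme gene ALDH1L2 8.35-fold and the cystine transporter gene SLC7A11 7.55-fold. The COPII coat gene SEC24D rose 7.08-fold, the endoplasmic reticulum co-chaperone gene DNAJB9 7.04-fold and TP53INP1 6.82-fold. Without detection calls it is not known whether dim values, such as NMRAL2P in vehicle (4.58) and FAM111B with LY101-4B (5.34), were above background, so such folds and their ranks are uncertain. The limma adjusted p of these 24 genes ranged from 0.0003 to 0.0019.

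**Figure D1:**
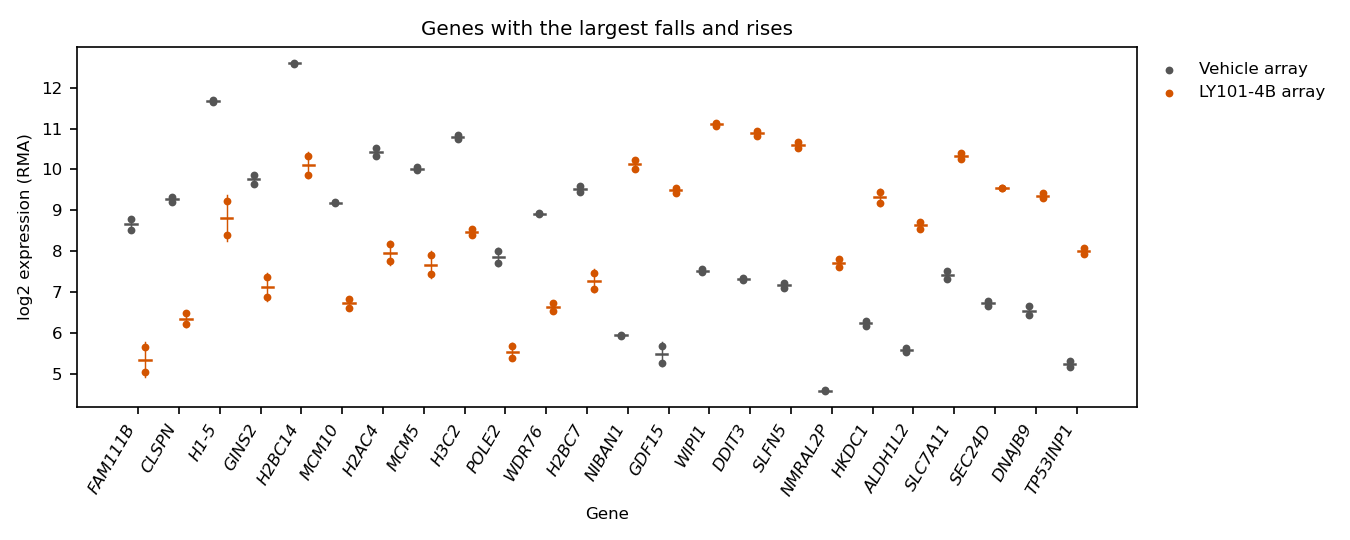
Log2 RMA expression (vertical axis) of the 12 genes with the largest falls and the 12 with the largest rises (horizontal axis), with each array as a point (grey, vehicle; orange, LY101-4B), the group mean as a horizontal bar and the SD (n = 2) as a vertical line. The arrays of the groups do not overlap for any of these genes, which were chosen to be so separated; FAM111B lies at 8.66 against 5.34 and NIBAN1 at 5.93 against 10.1.

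In total 1930 of 21214 probe sets rose and 2236 fell at a limma adjusted p under 0.05, and 338 and 344 of these changed by at least 2-fold. All of the called probe sets had non-overlapping groups, as did 58.0% of all tested probe sets. For a single probe set, chance gives 33.3% for 2 arrays against 2. Probe sets on the same 4 arrays vary together, so the 58.0% is not a test against chance. The size of the count depended on single arrays and on the rows tested: without vehicle replicate 1 it was 755 higher and 855 lower, without vehicle replicate 2 it was 874 and 811, and over all 33297 rows it was 1162 and 1271. In simulated data between 2.78% and 14.2% of calls were false with each probe set's own variance, with a mean of 8.05%. With variances drawn from the fitted prior the mean was 4.27%. Each draw changed only 200 probe sets, so these shares need not hold for the 4166 calls here. Single calls near the threshold can thus be less certain than their adjusted p states.

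Within the E2F family itself, 6 of 13 measured members of the E2F and pocket protein list fell, 0 rose and 7 did not pass. Adjusted over the list alone, 8 fell. The atypical repressor E2F8 fell 3.76-fold (-1.91 ± 0.13 log2 units, SE; limma adjusted p 0.001), RBL1, which encodes the pocket protein p107, fell 2.48-fold (adjusted p 0.002), and TFDP1, the dimerisation partner of E2F proteins, fell 1.80-fold (adjusted p 0.0025). The activator genes E2F1 and E2F2 fell 1.70-fold and 1.65-fold, and E2F4 fell 1.35-fold, each with a limma adjusted p of 0.020. These calls were less firm. Here and below, a fit without 1 array took its spread from fewer arrays, so a missed threshold there need not mean a smaller difference. E2F1 missed the threshold without vehicle replicate 2 and without either LY101-4B array (adjusted p 0.0797, 0.0887 and 0.0531), and E2F2 missed it without either vehicle array (0.0753 and 0.0873). E2F4 missed it without vehicle replicate 1, vehicle replicate 2 or LY101-4B replicate 1 (0.142, 0.154 and 0.0521). The log2 differences of E2F3 (-0.44 ± 0.13), E2F7 (-0.26 ± 0.09), RBL2 (-0.25 ± 0.13), TFDP2 (-0.20 ± 0.09), RB1 (-0.11 ± 0.11), E2F6 (0.03 ± 0.10, or -0.02 with arrays centred on their medians) and E2F5 (0.21 ± 0.14) did not pass. E2F3 passed at an adjusted p of 0.0244 and RBL2 at 0.048 when LY101-4B replicate 2 was left out. E2F3 also passed with median centring (0.048), the brighter 50% of probe sets (0.0261) and an intensity trend (0.0385), and E2F7 with the brighter 50% (0.0317). The list as a set lay lower by camera (mean -0.54 log2 units, adjusted p 0.00021; adjusted p = 0.389 with an estimated correlation).

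**Figure D2:**
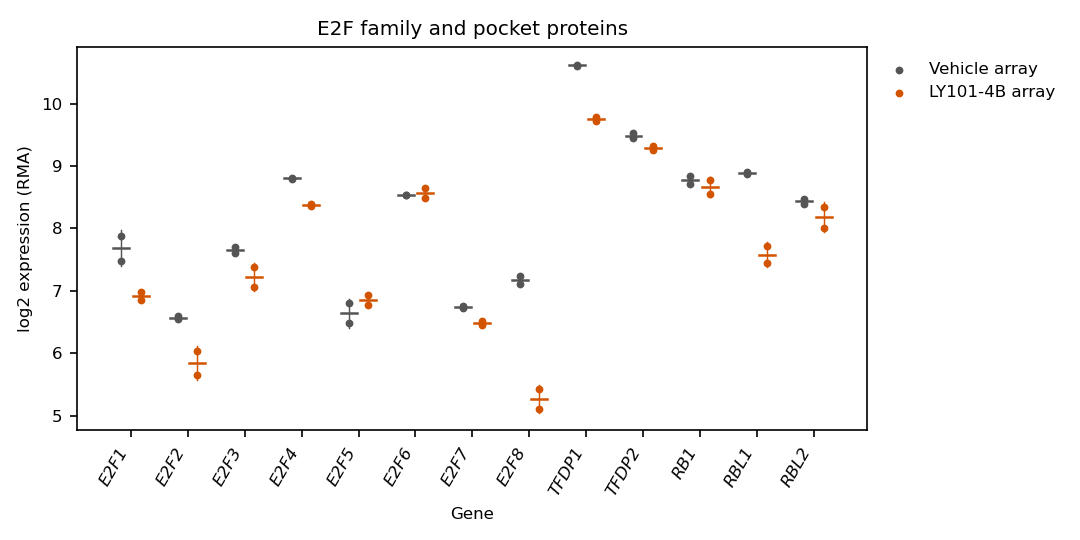
Log2 RMA expression (vertical axis) of 13 E2F family, dimerisation partner and pocket protein genes (horizontal axis) on each array (points; grey, vehicle; orange, LY101-4B), with group means (bars) and SD (vertical lines, n = 2). E2F8 and RBL1 show the widest separation, by 1.91 and 1.31 log2 units, and the E2F6 means differ by 0.03, or by -0.02 with arrays centred on their medians.

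Known E2F target genes of the G1/S transition fell almost throughout. Of 52 measured members, 50 fell, 0 rose and 2 did not pass, and all 52 fell when adjusted over the list alone. The mean difference was -1.56 log2 units, a 2.94-fold fall, and the list mean was -1.63 and -1.48 on the separate LY101-4B arrays against the vehicle mean. The members, with CLSPN, GINS2, MCM10 and MCM5 above among them, ranged from -2.93 for CLSPN to -0.21. The smallest falls were those of EZH2 (-0.21, limma adjusted p 0.154) and CDC6 (-0.26, limma adjusted p 0.098). Both were named after their values were seen, as the only members that did not pass over all genes. Camera gave an adjusted p of 1.7e-37 for this list; adjusted p = 0.289 with an estimated correlation, and 0.0085 by fry.

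Genes of mitosis, histones and DNA repair fell as well. In the G2/M list 42 of 44 members fell and 0 rose (42 adjusted over the list alone), with a mean of -1.07 log2 units (camera adjusted p 1.1e-27; adjusted p = 0.289 with an estimated correlation). CDK1, the mitotic kinase, fell 3.97-fold, the cytokinesis gene ANLN 3.96-fold, the kinetochore gene SPC25 3.53-fold and the spindle motor gene KIF11 2.85-fold, with limma adjusted p between 0.0006 and 0.0011. CKS2 (-0.01) and CDC25C (-0.15), named after their values were seen, did not pass. Among replication-dependent histone genes 23 of 33 fell and 0 rose (24 and 1 over the list alone), with a mean of -1.13 (camera adjusted p 2.3e-14; adjusted p = 0.289 with an estimated correlation). Histone genes are near-identical copies, so single members are uncertain. Of 37 DNA repair genes 22 fell and 2 rose, also over the list alone (mean -0.61, camera adjusted p 2e-09; adjusted p = 0.404 with an estimated correlation). The exonuclease gene EXO1 fell 4.30-fold, BRIP1 3.51-fold, the helicase gene BLM 3.25-fold and FANCB 3.08-fold. ERCC1 (0.75) and ATM (0.54), named after their values were seen, rose.

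The stress response governed by ATF4, which raises amino acid supply when translation is curbed, rose in 28 of 32 measured genes, with 0 falling and 4 not passing (28 over the list alone). Its mean difference was 1.40 log2 units, or 2.65-fold (camera adjusted p 2.2e-24; adjusted p = 0.289 with an estimated correlation). In addition to DDIT3, ALDH1L2 and SLC7A11, NUPR1, a stress-induced nuclear protein gene, rose 5.21-fold from 5.93 ± 0.01 to 8.32 ± 0.14 log2 units (SD, n = 2 each; limma adjusted p 0.0004). All 24 measured genes of the unfolded protein response rose, by 1.30 log2 units on average and by 0.41 to 2.82 (camera adjusted p 6.6e-22; adjusted p = 0.289 with an estimated correlation). Next to SEC24D and DNAJB9, the degradation factor gene HERPUD1 rose 5.05-fold and the chaperone gene HYOU1 3.61-fold.

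Oxidative stress genes under NRF2 rose in 16 of 25 cases and fell in 0 (17 and 0 over the list alone; mean 0.70, camera adjusted p 3.7e-09; adjusted p = 0.289 with an estimated correlation). HMOX1, haem oxygenase, rose 6.02-fold, the glutathione synthesis gene GCLC 3.63-fold and ME1 3.14-fold. The largest riser of the NRF2 list, SLC7A11, also stands on the ATF4 list. In the autophagy and lysosome list 11 of 29 rose and 3 fell (14 and 3 over the list alone; mean 0.52, camera adjusted p 4.6e-05; adjusted p = 0.300 with an estimated correlation). Along with WIPI1, the autophagy receptor gene SQSTM1 rose 3.96-fold, GABARAPL1 3.51-fold and MAP1LC3B 3.15-fold. CTSB (-0.48), ATP6V1A (-0.43) and ATG16L1 (-0.37) fell. These and the immediate early gene that fell were named after their values were seen. Immediate early genes rose in 11 of 23 cases and fell in 1 (14 and 2 over the list alone; mean 0.50, camera adjusted p 1.6e-06; adjusted p = 0.289 with an estimated correlation). They included ATF3 (3.55-fold), EGR1 (2.38-fold), JUND (2.28-fold) and FOSB (2.10-fold), and CCN1 fell by 0.88 log2 units. ATF3, the largest riser among them, also stands on the ATF4 list.

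Lipid synthesis genes rose in part. Cholesterol synthesis genes rose in 14 of 19 cases and fell in 1 (16 and 1 over the list alone; mean 0.78, camera adjusted p 4.3e-10; adjusted p = 0.289 with an estimated correlation), among them HMGCS1, an early enzyme of the pathway (3.85-fold), MSMO1 (3.36-fold), CYP51A1 (2.54-fold) and DHCR7 (2.51-fold). ACAT2 (-0.34) fell, as did GPAM (-0.65) and SCD5 (-0.35) of the fatty acid list and ADM (-0.46) of the hypoxia list, all named after their values were seen. In the fatty acid synthesis list 8 of 17 rose and 2 fell, also over the list alone (mean 0.42, median 0.12, camera adjusted p 0.0036; adjusted p = 0.387 with an estimated correlation), with ACSS2 at 2.53-fold, FADS1 at 2.45-fold, ELOVL7 at 2.31-fold and FADS2 at 2.23-fold. Of 23 hypoxia response genes 8 rose and 1 fell (9 and 1 over the list alone). The mean was 0.34 (camera adjusted p 0.001, or 0.300 with an estimated correlation). The rises were led by VEGFA (3.62-fold), NDRG1 (3.56-fold) and the glucose transporter gene SLC2A3 (1.96-fold). VEGFA also stands on the ATF4 list. INSIG2 rose 1.58-fold and missed the threshold without vehicle replicate 1 (adjusted p 0.079). Metallothionein-list genes rose in 3 of 9 cases (4 over the list alone; mean 0.28, camera adjusted p 0.006; adjusted p = 0.389 with an estimated correlation). MT1M rose 1.62-fold, the zinc exporter gene SLC30A1 1.46-fold and MT1H 1.25-fold. MT1M missed the threshold without vehicle replicate 1 (adjusted p 0.0525) and SLC30A1 without either vehicle array (0.132 and 0.0736), while MT1H missed it without any one of the 4 arrays (0.0761 to 0.29) and under cyclic loess (0.0626), median centring (0.0767), an intensity trend (0.0633) and a robust prior (0.0508).

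Of 31 ribosome biogenesis and MYC target genes 27 fell and 0 rose, also over the list alone (mean -0.58, camera adjusted p 2.3e-14; adjusted p = 0.289 with an estimated correlation), among them UTP20 (2.31-fold), MRTO4 (2.15-fold), RRS1 (2.04-fold) and BOP1 (1.96-fold). The ribosomal protein genes did not shift as a list (mean -0.01, median 0.02, camera adjusted p 0.828), and 2 of 33, RPL22 and RPL32, fell (1 over the list alone). RPL22 missed the threshold without either vehicle array (adjusted p 0.0636 and 0.0519) and RPL32 without any one of the arrays (0.0595 to 0.204); under cyclic loess this list lay higher, by 0.10 (camera adjusted p 0.0114). Oxidative phosphorylation genes fell in 12 of 35 cases and rose in 0 (20 and 0 over the list alone; mean -0.30, camera adjusted p 1.2e-06; adjusted p = 0.289 with an estimated correlation), with ATP5MC1 down 1.95-fold, NDUFB3 1.68-fold, NDUFB10 1.57-fold and SDHD 1.53-fold. NDUFB3 missed the threshold without either vehicle array (adjusted p 0.0735 and 0.0985), NDUFB10 without vehicle replicate 1 (0.0612) and SDHD without vehicle replicate 2 (0.0734). Heat shock genes fell in 10 of 17 cases and rose in 0 (12 and 1 over the list alone; mean -0.35, camera adjusted p 0.00011; adjusted p = 0.387 with an estimated correlation). HSPA4L lay 1.78-fold lower, HSPH1 1.55-fold, CHORDC1 1.53-fold and HSPE1 1.51-fold, with limma adjusted p from 0.0091 to 0.0313. HSPA4L, HSPH1 and CHORDC1 missed the threshold without either vehicle array, and HSPE1 without vehicle replicate 2, at adjusted p between 0.0755 and 0.113. Glycolysis genes did not pass as a list (mean -0.15, 3 rose and 4 fell of 16, or 3 and 5 over the list alone, camera adjusted p 0.0614); it passed with an intensity trend (0.00379), on ranks (0.0359) and by fry (0.0452). LDHA fell 1.60-fold and PFKM 1.72-fold, while HK2 rose 1.43-fold and ALDOC 1.40-fold. PFKM missed the threshold without vehicle replicate 1 (adjusted p 0.0542), and HK2 (0.111 and 0.0767) and ALDOC (0.109 and 0.122) without either vehicle array.

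**Figure D3:**
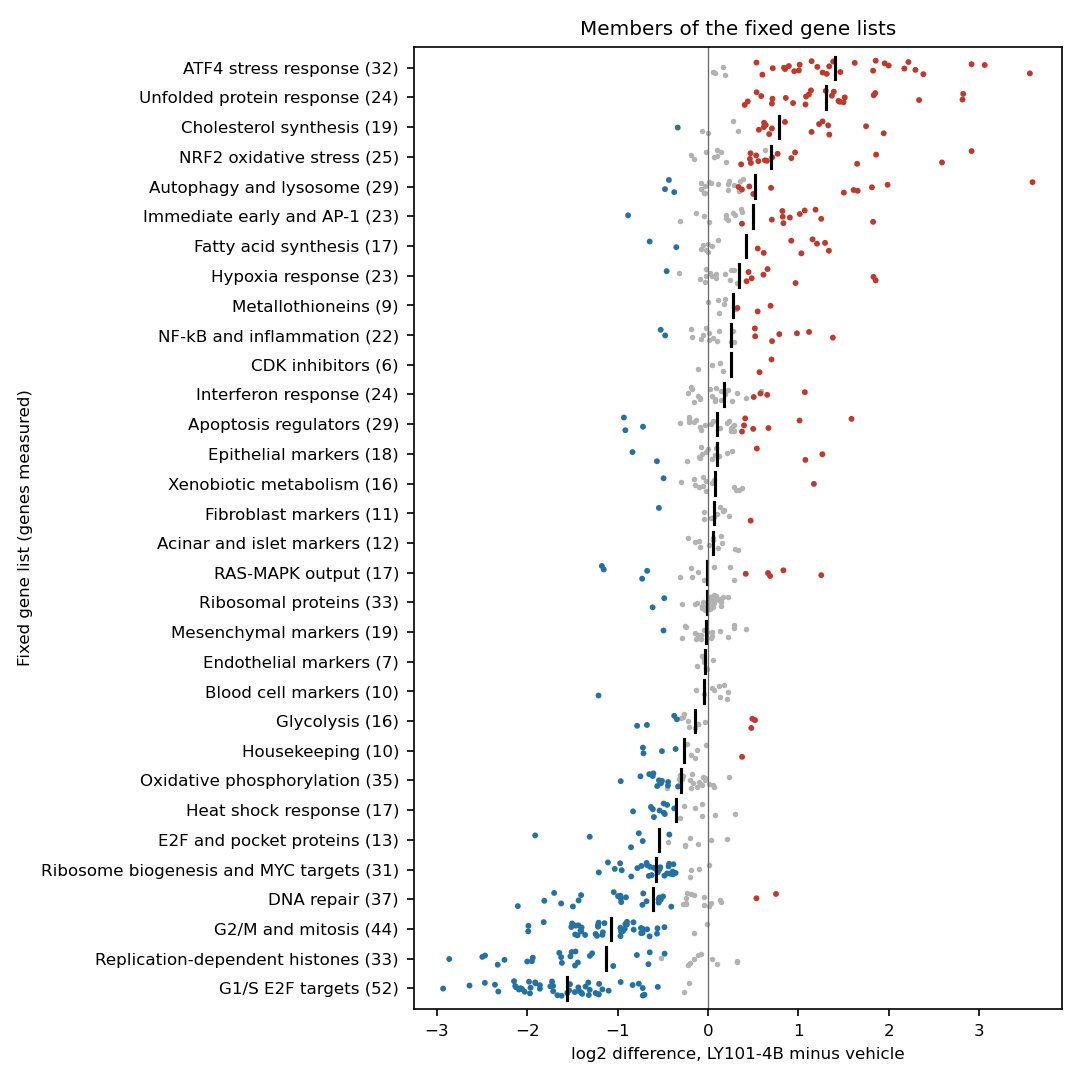
Log2 difference between LY101-4B and vehicle (horizontal axis) for each measured gene (points) of 32 fixed gene lists (vertical axis, number of genes measured in brackets). Red points rose and blue points fell at a limma adjusted p under 0.05, grey points did not pass, and black bars are list means, from 1.40 for the ATF4 list to -1.56 for the G1/S E2F targets.

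Signalling and death genes moved in both directions. In the NF-kB list 7 of 22 rose and 2 fell, also over the list alone (mean 0.26, camera adjusted p 0.017; adjusted p = 0.300 with an estimated correlation), and the set missed the threshold without LY101-4B replicate 1 (adjusted p 0.0511). CXCL2 rose 2.60-fold, LIF 2.17-fold, CXCL8 1.98-fold and IRF1 1.73-fold. CXCL1 (-0.52) and NFKB1 (-0.47), named after their values were seen, fell. Genes downstream of RAS and MAPK did not pass as a list (mean -0.01, or 0.04 under cyclic loess, camera adjusted p 0.905): 5 of 17 rose and 4 fell (7 and 5 over the list alone), with EGR1 up 2.38-fold and IER3 up 1.78-fold, and SPRY1 down 2.26-fold and CCND1, cyclin D1, down 2.23-fold. EGR1 and IER3 also stand on the immediate early list. Apoptosis regulators did not pass either (mean 0.10, camera adjusted p 0.18; 0.0395 without LY101-4B replicate 1), with 7 of 29 rising and 3 falling, also over the list alone. The death receptor gene TNFRSF10B rose by 1.59 log2 units and PMAIP1, which encodes NOXA, by 1.01, while CASP2 fell 1.91-fold and BIRC5, which encodes survivin, 1.88-fold. BIRC5 also stands on the G2/M list. Interferon response genes did not pass (mean 0.18, camera adjusted p 0.0701; 0.00809 without LY101-4B replicate 1), and 4 of 24 rose, also over the list alone. These were RSAD2, OASL, IFIT3 and ISG20, at 1.42-fold to 2.10-fold. RSAD2 (adjusted p 0.0582 and 0.0872), IFIT3 (0.0874 and 0.0672) and ISG20 (0.064 and 0.16) missed the threshold without either vehicle array, OASL without vehicle replicate 2 (0.0571) and ISG20 also without LY101-4B replicate 1 (0.0679). Of 6 CDK inhibitor genes CDKN1A (1.63-fold) and CDKN1B (1.48-fold) rose, and both calls were lost without either vehicle array (adjusted p 0.0551 to 0.0817); the list did not pass by camera (adjusted p 0.117) but did by fry (0.041). Of 16 xenobiotic metabolism genes CYP1B1 rose 2.25-fold and GSTM1 fell 1.41-fold, the latter missing the threshold without either vehicle array or LY101-4B replicate 2 (adjusted p 0.0545 to 0.16); the list did not pass (camera adjusted p 0.764).

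Markers of cell identity did not pass as lists by camera, though the epithelial list passed by fry (adjusted p 0.0285). Epithelial markers (mean 0.09, camera adjusted p 0.517) held 3 risers and 2 fallers among 18 genes: CLDN1 rose 2.40-fold and CLDN4 2.11-fold, while the keratin genes KRT8 and KRT18 fell 1.78-fold and 1.48-fold, the latter at adjusted p 0.0983 and 0.0527 without either vehicle array. The mesenchymal list had a camera adjusted p of 0.764, with AXL alone falling (1.41-fold), and the fibroblast list one of 0.301, with COL3A1 falling 1.46-fold and COL1A2 rising 1.39-fold. AXL and COL1A2 missed the threshold without either vehicle array (adjusted p 0.0931 and 0.139, and 0.139 and 0.102), and AXL also without LY101-4B replicate 1 (0.0535). COL3A1 missed it without vehicle replicate 1 or either LY101-4B array (0.188, 0.113 and 0.0531). Acinar and islet markers (0.673), blood cell markers (0.828) and endothelial markers (0.764) gave no call either, and among these last 3 lists only LYZ, lysozyme, passed singly, falling 2.32-fold. PTF1A (0.33) and CTRC (0.30) of the acinar and islet list and VWF (-0.13) and CDH5 (-0.06, or 0.03 without vehicle replicate 2) of the endothelial list, given as log2 differences, did not pass; PTF1A passed without LY101-4B replicate 2 (adjusted p 0.0291). Reference genes were not constant: of 10 measured, 4 fell and 1 rose, also over the list alone (mean -0.26, camera adjusted p 0.015; adjusted p = 0.389 with an estimated correlation), with HPRT1 down 1.65-fold, PPIA down 1.64-fold, SDHA down 1.42-fold and B2M up 1.30-fold. SDHA missed the threshold without either vehicle array (adjusted p 0.0842 and 0.11) and B2M without any one of the 4 arrays (0.0523 to 0.205). Of 10000 random gene lists matched on mean signal, 10.6% had a mean below that of the housekeeping list. The housekeeping list's call was lost under cyclic loess (mean -0.16, adjusted p 0.151) and with the brighter 50% of probe sets alone (adjusted p 0.0757).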

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

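The tests in this part were chosen after the results were seen, except the fit over all rows, which was planned.

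Probe sets to which the platform annotation gives no gene were left out of the comparisons above, yet some of them changed. In the fit over all 33297 rows, 163 of the 12083 unannotated probe sets were higher and 169 lower with LY101-4B, 57 and 38 of them by at least 2-fold, with changes from -2.90 to 3.76 log2 units. This is 2.75% of them, against 9.90% of annotated probe sets in the same fit. The unannotated probe sets were dimmer (mean log2 value 5.51 against 6.69), calls were fewer among dim probe sets, and control probe sets were not separated from the rest, so the shares are not like for like. They are not named here.

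Only 3 splits of the 4 arrays into 2 and 2 exist, too few for a share under 0.05. The real split, the 1 split that reached its own count, gave 4166 called probe sets, and the highest count of the other splits was 0. Each other split put a vehicle and an LY101-4B array in both groups. Any difference between the real groups then became spread within groups, so the count of 0 says nothing about chance.

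The first pattern is the fall of the G1/S E2F targets. Brighter probe sets lay lower with LY101-4B (median difference -0.088 log2 units in the brightest of 10 equal signal classes), so a signal-dependent bias was tested: 0 of 10000 random lists matched on mean signal had a mean as low as -1.56, their middle 95% running from -0.209 to 0.086. The tables therefore argue against this bias as the cause. The G1/S list fell by more than the G2/M list, with a difference of -0.486 log2 units (-0.491 and -0.481 on the separate LY101-4B arrays). A 2-sided permutation of genes gave p = 2e-05, although genes are not independent replicates. These values argue only against an equal fall of both lists. A loss of dividing cells need not lower every gene equally, so the difference cannot decide on it. A loss of dividing cells, an arrest that lowers G1/S transcripts more than G2/M transcripts, direct inhibition of E2F and a secondary effect of stress all stay open. There is 1 dose, 1 time and no measure of the cell cycle.

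The second pattern is the joint rise of the ATF4 and unfolded protein response lists, which include DDIT3, ALDH1L2, SLC7A11, SEC24D and DNAJB9. Signal-dependent bias was argued against, with 0 of 10000 matched lists reaching the joint mean of 1.36 over 56 genes. Whether this stress belongs to the compound's action on E2F, to another target or to the 50 µM dose was not tested.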

How the results depend on the processing

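The 1930 higher and 2236 lower probe sets stayed within 1.5 times under cyclic loess, median centring, the brighter 50% of probe sets, a trend or robust prior, 1 probe set per gene and single-symbol probe sets. With all rows, where both the adjustment and the fitted prior change, the counts were 1162 and 1271; which of these is the cause was not tested. With a 2-fold minimum they were 338 and 344, by construction. Leaving out 1 array gave 755 to 1899 higher and 811 to 2467 lower; the lone array of a group was then assumed to vary like the others. Deviations of same-numbered arrays correlated at 0.116 across probe sets, and 2 pairs do not show pairing. With a replicate block the counts were 2024 and 2312, and 3957 of the 4166 called probe sets remained called; E2F3 gained a call and MT1H lost its call (adjusted p 0.0385 and 0.0641), and no other named gene and no list changed its call. The G1/S E2F targets lay between -1.63 and -1.48 over the left-out arrays and kept their call in each alternative except camera with an estimated correlation (-1.56, adjusted p 0.289), under which 0 lists were called higher and 0 lower against 11 and 9. With only 2 residual degrees of freedom that test may have little power. Its estimated correlations among the called lists also ran from -0.044 for NF-kB to 0.57 for DNA repair, against the preset 0.01. For the G1/S list the estimate was 0.29. Low power and correlated genes were not told apart, and the small p-values with the preset correlation treat genes as nearly independent. Over the left-out arrays 11 to 12 lists were higher and 9 lower.

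Means that changed sign all lay near 0. Ribosomal proteins turned to 0.10 under cyclic loess, where the list passed, and to 0.0094 without vehicle replicate 1 (-0.025 to 0.0094 over the left-out arrays); the cause was not tested. None of the others passed a threshold. With the brighter 50% of probe sets, xenobiotic metabolism was -0.13 and blood cell markers 0.14. That filter removes dim list members and leaves the differences of the others as they were, so these 2 sign changes come from membership. For the rest the cause was not tested. RAS and MAPK output was 0.039 under cyclic loess and 0.053 without LY101-4B replicate 1 (lowest -0.066). Acinar and islet markers were -0.00094 after median centring. Blood cell and endothelial markers were 0.030 and 0.018 without LY101-4B replicate 2 (lowest -0.11 and -0.092). E2F6 was -0.016 after median centring and -0.046 without LY101-4B replicate 2 (highest 0.12), and CDH5 was 0.026 without vehicle replicate 2 (lowest -0.15). Camera's direction differed from the sign of the mean for ribosomal proteins, RAS and MAPK output and blood cell markers, and mean and median differed in sign for ribosomal proteins, xenobiotic metabolism and blood cell markers. Of the 128 genes the naming rule takes over all lists, 28 and 27 lost their call without vehicle replicates 1 and 2, and 8 and 6 without LY101-4B replicates 1 and 2. Calls went with signal: of 10 equal signal classes, the dimmest had 1.98% of its probe sets called and the brightest 41.6%, and whether low signal or a lack of change caused this was not tested.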

Other observations

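The lists in this part were chosen after the data were seen, so their tests describe these arrays only. Their camera p-values, with either correlation, were adjusted only over the lists of this part, not together with the fixed lists above. Where genes of earlier lists were left out, the adjustment was made again over the resulting lists. These adjusted p-values are thus not directly comparable with those of the fixed lists. Of 20 COPII coat and export genes 15 rose and 0 fell (17 and 0 over the list alone). The mean was 0.70 log2 units (camera adjusted p 5.6e-11, or 0.109 with an estimated correlation). In addition to SEC24D, SEC23B rose by 1.03. KDELR3, whose product returns proteins to the endoplasmic reticulum rather than exporting them, rose by 1.62. SEC24D and SEC31A also stand on the unfolded protein response list, and of the 18 genes that stand on no earlier list 13 rose and 0 fell (15 and 0 over the list alone; mean 0.56, camera adjusted p 4.7e-09; adjusted p = 0.124 with an estimated correlation). Amino acid transporter genes rose in 11 of 16 cases (12 over the list alone, where 2 fell; mean 0.88, camera adjusted p 4.3e-08; adjusted p = 0.109 with an estimated correlation), among them SLC1A4 by 2.69, SLC43A1 by 1.53 and SLC6A9 by 1.15. SLC3A2, SLC7A1, SLC7A5, SLC7A11 and SLC38A2 also stand on the ATF4 list, and of the other 11 transporters 7 rose and 0 fell (8 and 2 over the list alone; mean 0.70, camera adjusted p 0.00012; adjusted p = 0.124 with an estimated correlation).

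Of 19 genes for cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, 9 rose and 3 fell (10 and 4 over the list alone), with WARS1 up by 1.31 and SARS1 by 1.01 and FARSB at -0.61 log2 units. Of 16 mitochondrial members 10 fell and 0 rose (11 and 1 over the list alone), with LARS2 at -1.06 and MARS2 at -0.89. The means were 0.282 (camera adjusted p 0.011; adjusted p = 0.455 with an estimated correlation) and -0.401 (camera adjusted p 3.4e-05; adjusted p = 0.306 with an estimated correlation), a difference of 0.683 (2-sided permutation of genes, p = 0.0001). AARS1, CARS1, GARS1, NARS1, SARS1 and WARS1 also stand on the ATF4 list, and the rise of the cytosolic list was not seen outside them: of the other 13 members 4 rose and 3 fell (5 and 4 over the list alone; mean 0.03, median -0.04, camera adjusted p 0.759). The mean of these 13 lay above that of the mitochondrial members by 0.433 (2-sided permutation of genes, p = 0.004). Both permutations exchanged genes as if they were independent. Camera estimated correlations of 0.48 within the 13 and 0.47 within the mitochondrial list. Genes are not independent replicates, so these 2 permutation p-values can be too small and do not measure spread between cultures.

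Chromosome structure genes fell with the mitotic list. All 15 centromere protein genes fell (mean -0.97, camera adjusted p 1.6e-11; adjusted p = 0.109 with an estimated correlation), as did 13 of 20 cohesin and condensin genes while 1 rose (mean -0.86, camera adjusted p 4.7e-09; adjusted p = 0.208 with an estimated correlation). Within the latter, the condensin gene NCAPH lay at -1.91 and the cohesin acetyltransferase gene ESCO2 at -2.12, whereas ESCO1, its paralogue, rose by 0.66; STAG1 (-0.03) and the loader gene NIPBL (-0.02) did not pass.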
